A study of Mus musculus with 6 samples.

How the data were processed

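Per the labels, total RNA was prepared from freshly dissected adult mouse testis with TRIzol and a column kit, and its quality was checked on a Bioanalyzer. Biotin-labelled cRNA made from 4 µg of it, per the labels, was hybridised to Affymetrix whole-genome mouse expression arrays, 1 array for each of 3 wild-type and 3 DREAM transgenic samples. The submitters' processing notes name RMA (background correction, quantile normalization and a summary of the probes of each probe set) and the affy package, with no version or parameters. The deposited values are log2 intensities per probe set, given to 2 decimals, per the submitters' notes and the range of the values. RMA forces the arrays to a near-common distribution, so a shift of all transcripts at once cannot be seen, and it gives no detection call, so a low value is not a statement that a transcript is absent. No genome build is given in the sources used here and no coordinates are printed.

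The value table holds 45101 probe sets, of which 64 Affymetrix controls were left out of the tests and the remaining 45037 were all tested, with no filter on dim probe sets. Gene names come from the platform annotation given for these arrays: 34945 probe sets carry 1 gene, 932 several and 9160 none here. Symbols were brought up to date, and chromosomes and neighbours taken, from an NCBI RefSeq gene table of assembly GRCm38.p6, which matched 34741 of the single-gene probe sets. Probe sets with several genes were counted and never named.

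Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), as transgenic minus wild type, with Benjamini-Hochberg adjustment over the 45037 probe sets and a threshold of adjusted p under 0.05. Replicate errors are SDs over 3 arrays. Rules fixed before the data were examined named Kcnip3, the 12 genes with the largest increase and the 12 with the largest decrease among calls with 1 gene symbol and non-overlapping groups (1 probe set per gene, the one of smallest p, leaving out clone-style symbols). In each fixed list they named the members past the threshold (at most 4) or else the 2 of smallest p. 52 genes were eligible as higher and 73 as lower, and 5 and 16 more were left unnamed for their symbols. Members that passed only adjusted over their list alone, other probe sets of named genes, Star, Cyp17a1, Cyp11a1, Serpina5 and Zfp386 were named after their values were seen. Clauses on what a gene does are background.

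The 30 gene lists, also fixed before the data were examined, were tested with camera at a preset inter-gene correlation of 0.01 over a table of 18193 genes, each represented by its brightest single-gene probe set over all 6 arrays, with Benjamini-Hochberg adjustment over the 30 lists. Camera with an estimated correlation and fry, which asks whether the genes of a set move on balance in 1 direction without comparing them with other genes, stand beside it. 0 of the lists passed either. Called genes per chromosome were compared with all measured genes by Fisher's exact test. RNA integrity was taken from the 3' minus 5' log2 difference of the Gapdh and beta-actin control probe sets and compared by an exact permutation test, which cannot give p under 0.1 for 3 against 3.

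The alternatives were filters dropping the lowest 40% or 60% of probe sets, quantile normalization again, median centring, trend and robust eBayes, array weights, the replicate number as a block, leaving out each array, leaving out probe sets of names ending in _x_at, _s_at or _a_at, looser and fold-change thresholds and averaging a gene's probe sets. Added after the data were seen were the Gapdh difference as a covariate and the MHC list without its members outside chromosome 17. The tests were checked on simulated values for 45037 probe sets of 3 against 3 arrays, with 200 changed: 96% of the 2-fold and 100% of the 4-fold changes were recovered, and 6.67% of the calls were false. The simulated noise was independent between probe sets and held no outlying array, so these shares are not error rates of the real data. No array's values were a copy of another's.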

Results

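Gene expression was measured in freshly dissected testes of adult mice on 6 Affymetrix whole-genome mouse expression arrays, 3 from wild-type mice and 3 from mice carrying a DREAM transgene, all of a hybrid C57BL/6 and CBA background. DREAM, also called KChIP3 or calsenilin and encoded by Kcnip3, is a calcium-binding protein of the neuronal calcium sensor family that represses transcription when free of calcium. The transgene carries a mutant described as constitutively active. The deposited values are log2 intensities, and their median per array ran from 5.99 to 6.08. The first principal component, with 39.0% of the variance, set wild type replicate 2 apart at 42.2 (the other 5 arrays lay between -23.3 and 5.3), and the second, with 27.2%, separated the genotypes. The precision of every value below is limited by the number of arrays, 3 per group, described by the submitters as independent biological replicates.

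The comparison of transgenic with wild-type testis asks which transcripts differ when the active form of DREAM is present. Kcnip3 itself, on chromosome 2, read 7.21 ± 0.11 in wild type and 7.27 ± 0.11 in transgenic testis (log2, SD, n = 3) with its brighter probe set, a difference of 0.06 (SE 0.10, limma adjusted p = 0.974, 95% interval -0.16 to 0.29). Its other probe set read 6.04 ± 0.07 and 6.18 ± 0.14, a difference of 0.14 (SE 0.10, adjusted p = 0.909, 95% interval -0.08 to 0.37). Neither passed the test, and the groups overlapped with both probe sets. Whether these probe sets match the transgene's transcript is not known from the sources used here, so they do not check the genotype labels.

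The largest named increases were those of Sult1e1, Serpina1c, Serpina3a and Hsd3b1, in transgenic against wild-type testis. Sult1e1, which encodes estrogen sulfotransferase, rose 3.91-fold, from 6.80 ± 0.33 to 8.76 ± 0.20 (log2, SD, n = 3 per group; chromosome 5, log2 change 1.97, SE 0.17, adjusted p = 0.00103). Serpina1c, an alpha-1-antitrypsin gene, rose 3.86-fold, from 5.20 ± 0.25 to 7.15 ± 0.10 (chromosome 12, log2 change 1.95, SE 0.13, adjusted p = 0.000288). Serpina3a, of the antichymotrypsin branch of that family, rose 3.57-fold, from 8.94 ± 0.10 to 10.77 ± 0.05 (chromosome 12, log2 change 1.84, SE 0.09, adjusted p = 4.85e-05). Serpina1b rose 2.41-fold with 1 probe set (adjusted p = 0.00452) and by 0.99 on the log2 scale with its other probe set (adjusted p = 0.0112). Both are of a class that can match several transcripts, so the alpha-1-antitrypsin copies may not be told apart. Hsd3b1, a 3-beta-hydroxysteroid dehydrogenase of steroid hormone synthesis, rose 2.80-fold, from 8.38 ± 0.23 to 9.86 ± 0.11 (chromosome 3, log2 change 1.48, SE 0.13, adjusted p = 0.00109). The other named increases were Fmn1 (an actin-nucleating formin, 2.72-fold), Tspan18 (a tetraspanin, 2.34-fold), Gcsh (the H protein of the glycine cleavage system, 2.25-fold), Mthfd2l (a mitochondrial folate enzyme, 2.18-fold), Ssh1 (a cofilin phosphatase, 2.16-fold), Kcnab1 (a beta subunit of voltage-gated potassium channels, 2.10-fold) and Plppr1 (2.10-fold), with adjusted p from 0.000493 to 0.0161.

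Among the 12 named decreases, those of Pdxdc1 and Tmem267 were the largest. Pdxdc1, a gene for a protein with a pyridoxal-dependent decarboxylase domain, fell 15.8-fold in intensity with 1 probe set on chromosome 16, from 9.41 ± 0.37 to 5.43 ± 0.06 (log2, SD, n = 3 per group; log2 change -3.98, SE 0.17, adjusted p = 2.01e-05). Another probe set of Pdxdc1 rose by 0.72 (SE 0.08, adjusted p = 0.00774), and its others read 0.44 and 0.25 (adjusted p = 0.258 and 0.631), so the gene has no single direction. Tmem267, a transmembrane protein gene on chromosome 13, fell 11.8-fold, from 9.89 ± 0.12 to 6.33 ± 0.30 (log2 change -3.56, SE 0.15, adjusted p = 2.01e-05). Cst9, a cystatin gene of Sertoli cells, fell 5.10-fold, from 10.31 ± 0.20 to 7.96 ± 0.07 (chromosome 2, log2 change -2.35, SE 0.11, adjusted p = 4.85e-05). Apoc2, which encodes an activator of lipoprotein lipase, fell 4.00-fold, from 8.19 ± 0.11 to 6.19 ± 0.12 (chromosome 7, SE 0.10, adjusted p = 4.85e-05). The intensities of the opposite-strand transcripts Smc2os, Aknaos and Hoxb5os fell 6.06-fold, 3.87-fold and 3.66-fold (adjusted p = 4.85e-05, 4.85e-05 and 0.00573). Rd3, a regulator of retinal guanylate cyclase, fell 5.55-fold (adjusted p = 0.00048). Galc, a lysosomal galactosylceramidase, fell 4.52-fold (adjusted p = 7.16e-05) and Uqcr10, a subunit of respiratory complex III, fell 4.47-fold (adjusted p = 0.000187). Rcbtb2 fell 3.54-fold (adjusted p = 0.00451) and Qrich1 fell 3.31-fold (adjusted p = 0.0111). These folds are ratios of intensities, with no detection call. The low readings of Pdxdc1 (5.43), Galc (5.36) and Smc2os (3.98) in transgenic testis, and of Serpina1c (5.20), Plppr1 (4.91) and Serpina1b (4.79) in wild type, are not shown to lie above background, so the ratios of their transcripts are not known.

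**Figure D1:**
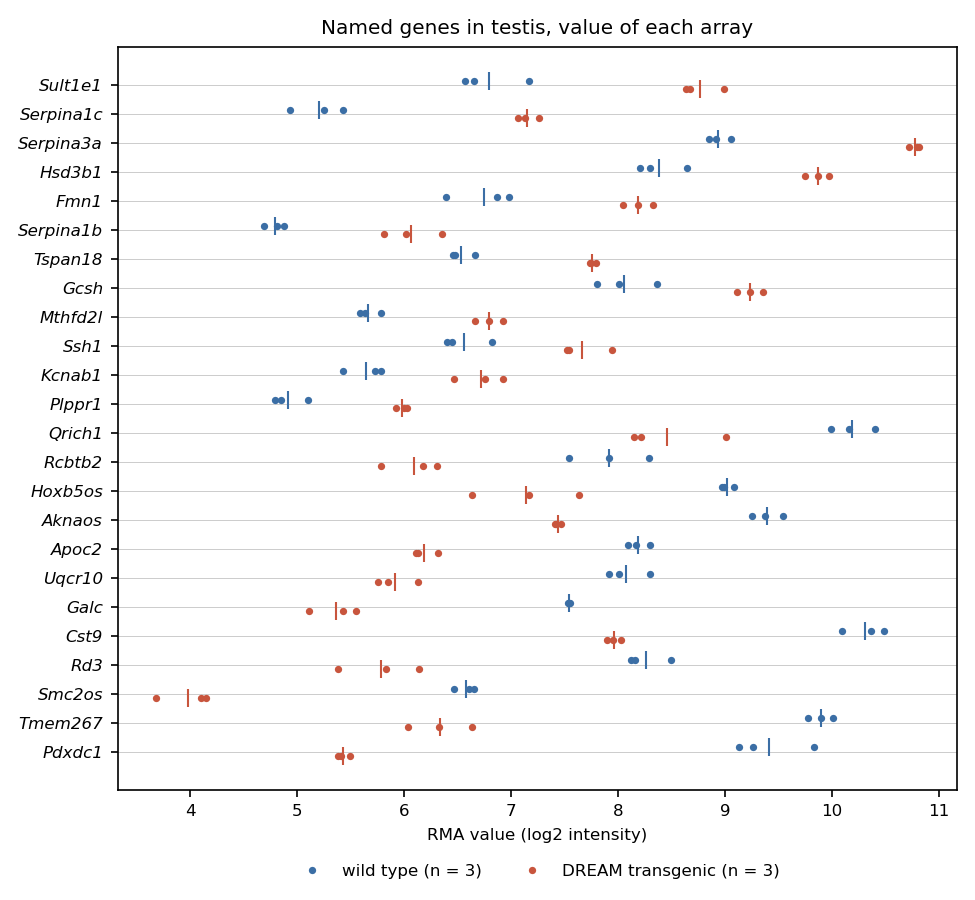
Deposited log2 intensity (horizontal axis) of each of the 6 arrays for the 12 named genes with the largest increase and the 12 with the largest decrease. Genes with clone-style symbols, such as 2010109A12Rik (log2 change -3.29), were left out. Points are arrays, short bars are group means, wild type in blue and DREAM transgenic in red. For each of these genes the 3 transgenic arrays lie wholly above or wholly below the 3 wild-type arrays, most widely for Pdxdc1 at means of 9.41 and 5.43.

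Several of these genes had further probe sets that moved less than the named probe set and did not pass. Galc read -0.31 with its other bright probe set, in the same direction and with non-overlapping groups (unadjusted p = 0.00658, adjusted p = 0.354). Uqcr10 read -0.68 with another probe set, again with non-overlapping groups (unadjusted p = 0.00229, adjusted p = 0.198), and 0.04 with its brightest (adjusted p = 0.982). Tspan18 read -0.05 and 0.08 with its others (adjusted p = 0.984 and 0.965). Rcbtb2 read -0.03 with its other bright probe set (adjusted p = 0.989), and -0.68, -0.08 and 0.06 with dimmer ones (adjusted p = 0.0733, 0.977 and 0.978). Ssh1 read 0.12, -0.11 and -0.01 with its 3 others, the smallest adjusted p being 0.904. Mthfd2l rose with another probe set as well, a dim one (log2 change 0.49, adjusted p = 0.0468), and read 0.80 and 0.00 with its 2 others (adjusted p = 0.0767 and 1). Kcnab1 read 0.55 with its other probe set (adjusted p = 0.0773), and Plppr1 0.43, 0.22 and 0.08 (adjusted p = 0.246, 0.72 and 0.973). Fmn1 read 0.05 and Rd3 -0.18 with theirs (adjusted p = 0.98 and 0.833), and Galc -0.10 with its dimmest (adjusted p = 0.94). Sult1e1, Serpina1c, Serpina3a, Hsd3b1, Gcsh, Tmem267, Smc2os, Cst9, Apoc2, Aknaos, Hoxb5os and Qrich1 had no other probe set that carries their gene alone. The change of each of them rests on 1 probe set. Over the 60 called genes with at least 1 other bright probe set, the called probe sets moved by a median of 0.905 on the log2 scale and the others by 0.143 in the same direction (95% interval 0.067 to 0.307). The called probe sets were picked for the smallest p, which by itself favours a larger change than in the others. The others moved by 0.0685 against a called size of 1.08 in the 38 genes called lower and by 0.267 against 0.834 in the 22 called higher. In 13 of the 60 genes they moved the opposite way, and in 12 at least 0.5 times as far the same way. Of the 105 other probe sets, 8 passed in the called direction and 1, of Pdxdc1, in the opposite one.

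**Figure D2:**
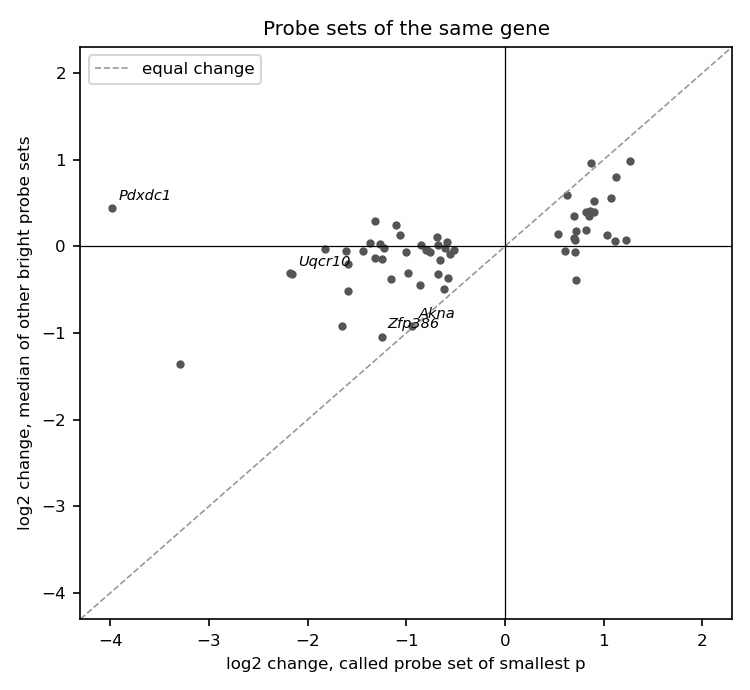
Log2 change of the called probe set of smallest p (horizontal axis) against the median log2 change of the same gene's other bright probe sets (vertical axis); each point is 1 of the 60 called genes that have another bright probe set, and the dashed line marks equal change. Most genes lie nearer to 0 on the vertical axis, as Uqcr10 does, while Akna and Zfp386 lie close to the dashed line and Pdxdc1 has the opposite sign.

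In all, 200 of 45037 probe sets differed at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 77 higher and 123 lower in transgenic testis, and 76 of them by at least 2-fold, 18 higher and 58 lower. They name 145 distinct genes, among which are Sult1e1, Hsd3b1, Cst9 and Apoc2. Of these genes 57 were higher and 89 lower, with Pdxdc1 in both counts. All 200 had non-overlapping groups, as did 5089 of all probe sets (11.3%, where chance gives 10%). An unadjusted p under 0.05 was reached by 3015 probe sets, against 2252 by chance. The count was 70, 71, 75 and 73 without wild type replicate 3 and transgenic replicates 1, 2 and 3. Without wild type replicate 2 it was 429, with more of them higher (239) than lower (190). Leaving out wild type replicate 3, transgenic replicate 2 or transgenic replicate 3 ended the calls of Gcsh, Ssh1, Kcnab1 and Qrich1 (adjusted p = 0.0626, 0.0913, 0.12 and 0.101 without transgenic replicate 2). Leaving out transgenic replicate 1 ended those of Gcsh (0.0755), Ssh1 (0.0776) and Hoxb5os (0.0513). With the Gapdh 3' minus 5' difference of each array as a covariate, an alternative chosen after the data were seen, 18 probe sets passed. Of the 17 named genes lost there, 9 had a change at least as large as before, Rd3 at -2.81 (SE 0.35) among them. The SEs of the 17 changed by a median of 1.78 times.

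Calcium mobilization is a subject of the study's title, and no fixed list of calcium genes passed. None of the 41 measured genes for calcium channels, pumps and release passed (5 at an unadjusted p under 0.05; none adjusted over the list alone; camera adjusted p = 0.854). The smallest p belonged to Cacna1c, an L-type channel subunit, at 5.74 ± 0.10 and 6.13 ± 0.23 (log2 difference 0.39, SE 0.13, adjusted p = 0.451). Trpc2 followed (0.20, SE 0.08, adjusted p = 0.72). None of the 32 genes for calcium binding and calmodulin signalling passed, 0 of them at an unadjusted p under 0.05 and 0 adjusted over the list alone (limma; camera adjusted p = 0.538). Hpca read -0.19 (adjusted p = 0.786) and Camk2a 0.19 (adjusted p = 0.855). Of the 18 measured genes reported elsewhere as DREAM targets, 0 passed, 0 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone (limma; camera adjusted p = 0.823). Npas4 read 0.15 (adjusted p = 0.936) and Slc8a3 -0.11 (adjusted p = 0.945). Measured means here that a probe set exists, with no detection call. A target not expressed in testis could not be seen to fall.

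Among DREAM's relatives and partners, Kcnip4 fell by 0.68 on the log2 scale with 1 of its probe sets (SE 0.12, adjusted p = 0.0468), at the low levels of 4.70 ± 0.20 and 4.02 ± 0.08. Its brighter probe set read -0.32 (adjusted p = 0.565) and another -0.51 (adjusted p = 0.186). Kcnip2, a subunit of Kv4 potassium channels, read -0.36 (SE 0.12, adjusted p = 0.48). With 1 brightest probe set per gene, 0 of the 7 measured members passed, 0 adjusted over the list alone and 2 at an unadjusted p under 0.05 (limma; camera adjusted p = 0.54).

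Among germ cell lists, the meiotic spermatocyte list was lower in transgenic testis, with 29 of 34 measured members below 0 and a median of -0.09 (camera adjusted p = 0.0021; adjusted p = 0.648 with an estimated correlation). No member passed over all genes, and 7 had an unadjusted p under 0.05 (limma). Adjusted over the list alone, 1 passed, and it was higher: Mybl1, a transcription factor of meiosis, at 7.87 ± 0.23 and 8.58 ± 0.18 (log2 difference 0.71, adjusted p = 0.0852 over all probe sets). Meiob, a meiotic recombination gene, read -0.58 (adjusted p = 0.303). The acrosome and sperm-egg binding list was also lower, with 24 of 34 members below 0 and a median of -0.04 (camera adjusted p = 0.0465; adjusted p = 0.648 with an estimated correlation). Of its members 0 passed over all genes or adjusted over the list alone, and 2 had an unadjusted limma p under 0.05. Izumo1, the sperm protein that binds the egg, read -0.28 (adjusted p = 0.476) and Tex101, which the meiotic list also holds, -0.20 (adjusted p = 0.743). Without wild type replicate 2 the camera adjusted p was 0.128 for the meiotic and 0.142 for the acrosome list. With the acrosome list, the call was also lost when the lowest 60% of probe sets were dropped (0.0756), after quantile normalization again (0.0931), without probe sets that can match several transcripts (0.145) and with averaged probe sets (0.0663). It was lost as well without wild type replicates 1 (0.0764) and 3 (0.129) and transgenic replicates 1 (0.273) and 3 (0.0573). The Gapdh 3' minus 5' difference, a measure of RNA integrity, was 0.11 ± 0.05 in wild type and 0.27 ± 0.06 in transgenic testis (SD, n = 3). With it as a covariate the meiotic mean went from -0.10 to 0.04 (adjusted p = 0.851), while the acrosome mean stayed at -0.04 (adjusted p = 0.38).

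The spermatogonia (18 measured members), round spermatid (26) and elongating spermatid (29) lists did not pass (camera adjusted p = 0.939, 0.204 and 0.764). Of their members 0 were past the threshold over all genes or over the list alone. An unadjusted limma p under 0.05 was reached by 0, 1 and 2 members. Zbtb16 read 0.17 and Lin28a -0.30 among spermatogonial genes (adjusted p = 0.83 and 0.85). Brdt read 0.33 and Taf7l -0.23 among round spermatid genes (adjusted p = 0.232 and 0.789), and Car4 -0.30 and Spem1 0.21 among elongating spermatid genes (adjusted p = 0.53 and 0.72). In the flagellum axoneme list, 1 of 36 members passed adjusted over the list alone, the dynein Dnah8 at -0.44 (adjusted p = 0.103 over all probe sets; camera adjusted p = 0.439). Akap3, which the CREM list also holds, read 0.28 (adjusted p = 0.388), and 2 members had an unadjusted p under 0.05.

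Among somatic cell lists, the Leydig cell list was higher, with 10 of 14 members above 0, a median of 0.08 and a mean of 0.22 (camera adjusted p = 0.0465; adjusted p = 0.785 with an estimated correlation). Hsd3b1 passed over all genes, and adjusted over the list alone Ptgds (0.45), Hsd17b3 (0.91) and Klk1b27 (-0.37) passed as well. Star, Cyp17a1 and Cyp11a1, at the core of testosterone synthesis, read 0.01, 0.03 and -0.06 (adjusted p = 0.995, 0.99 and 0.982). Adipose genes were higher as a set, 10 of 10 above 0 with a median of 0.20 (camera adjusted p = 0.00971; adjusted p = 0.648 with an estimated correlation). Of them 0 passed over all genes or adjusted over the list alone, and 1 had an unadjusted limma p under 0.05. Lpl read 0.41 and Retn 0.20 (adjusted p = 0.512 and 0.785). Endothelial genes were higher as a set, 11 of 12 above 0 with a median of 0.17 (camera adjusted p = 0.0173; adjusted p = 0.648 with an estimated correlation). Of them 0 passed over all genes, 4 had an unadjusted limma p under 0.05 and Tek (0.47, adjusted p = 0.237) passed adjusted over the list alone. Emcn read 0.24 (adjusted p = 0.685). Without wild type replicate 2 the camera adjusted p was 0.0543 for Leydig, 0.142 for adipose and 0.216 for endothelial genes. The Leydig list was also lost without wild type replicates 1 (0.17) and 3 (0.129) and transgenic replicates 1 (0.202) and 3 (0.0573). Dropping the lowest 40% of probe sets took the endothelial mean from 0.15 to 0.09 (adjusted p = 0.461), and that call was also lost without probe sets that can match several transcripts (0.145) and with averaged probe sets (0.0663). The adipose call was lost without the lowest 60% of probe sets (mean 0.16, adjusted p = 0.202), and the Leydig call without probe sets that can match several transcripts (mean 0.24, adjusted p = 0.0541). With the Gapdh 3' minus 5' difference as a covariate these lists moved apart: the Leydig mean went from 0.22 to 0.39 (adjusted p = 0.0697), the adipose mean went from 0.22 to 0.13 (adjusted p = 0.826) and the endothelial mean from 0.15 to 0.003 (adjusted p = 0.851).

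Sertoli cell genes did not move as a set (23 measured, camera adjusted p = 0.642, median 0.01, mean -0.08). Cst9 alone among them passed, over all genes and over the list alone, and Aard read -0.23 (adjusted p = 0.77). Peritubular myoid genes (12, camera adjusted p = 0.764) had 0 passing by either adjustment and 2 at an unadjusted limma p under 0.05. Myh11 read -0.33 and Casq2 0.19 (adjusted p = 0.612 and 0.735). Of 12 epididymal genes (camera adjusted p = 0.734), Lcn2, an iron-siderophore-binding lipocalin, rose from 10.68 ± 0.16 to 11.66 ± 0.24 (SD, n = 3; log2 change 0.98, SE 0.14, adjusted p = 0.0172, but 0.0634 without wild type replicate 3 and 0.118 and 0.101 without transgenic replicates 1 and 2). Rnase10 read -0.60 (adjusted p = 0.0647) and passed adjusted over the list alone. Erythroid genes (7, camera adjusted p = 0.912) had 0 members passing by either adjustment or at an unadjusted limma p under 0.05. Hba-a1 read 0.06 and Bpgm 0.05 (adjusted p = 0.971 and 0.974).

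The MHC region list was higher, with 13 of 17 members above 0 and a median of 0.21 (camera adjusted p = 0.00352; adjusted p = 0.648 with an estimated correlation). The list also holds B2m (0.29) and Cd74 (0.26), which lie on chromosomes 2 and 18; its 15 members on chromosome 17 had a median of 0.08 and a mean of 0.19 (camera adjusted p = 0.0103, an alternative added after the data were seen). H2-K1, a classical class I gene on chromosome 17, rose from 8.94 ± 0.15 to 9.65 ± 0.03 (SD, n = 3; log2 change 0.72, SE 0.10, adjusted p = 0.0182, but 0.0971 without wild type replicate 3 and 0.127, 0.12 and 0.114 without transgenic replicates 1, 2 and 3). H2-D1 (0.51), H2-Aa (0.78) and H2-Ab1 (0.40) passed adjusted over the list alone. Probe sets of H2-D1 ran from -1.01 to 0.51, and without probe sets that can match several transcripts the list mean was 0.05 (adjusted p = 0.754). Without wild type replicate 2 the list had an adjusted p of 0.163, with array weights of 0.101, and with the Gapdh 3' minus 5' covariate a mean of 0.11 (adjusted p = 0.854). Among 17 macrophage genes (camera adjusted p = 0.056), Fcgr3, an activating Fc receptor gene, fell from 8.92 ± 0.07 to 8.10 ± 0.22 (log2 change -0.82, SE 0.12, adjusted p = 0.0224, but 0.138 without wild type replicate 3 and 0.158 and 0.142 without transgenic replicates 2 and 3). Of the 17 genes 15 lay above 0, and Lyz2 (0.36) passed adjusted over the list alone. Interferon response genes (21, camera adjusted p = 0.207) had 0 passing by either adjustment and 3 at an unadjusted limma p under 0.05. Stat2 read -0.33 and Iigp1 0.31 (adjusted p = 0.531 and 0.609).

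**Figure D3:**
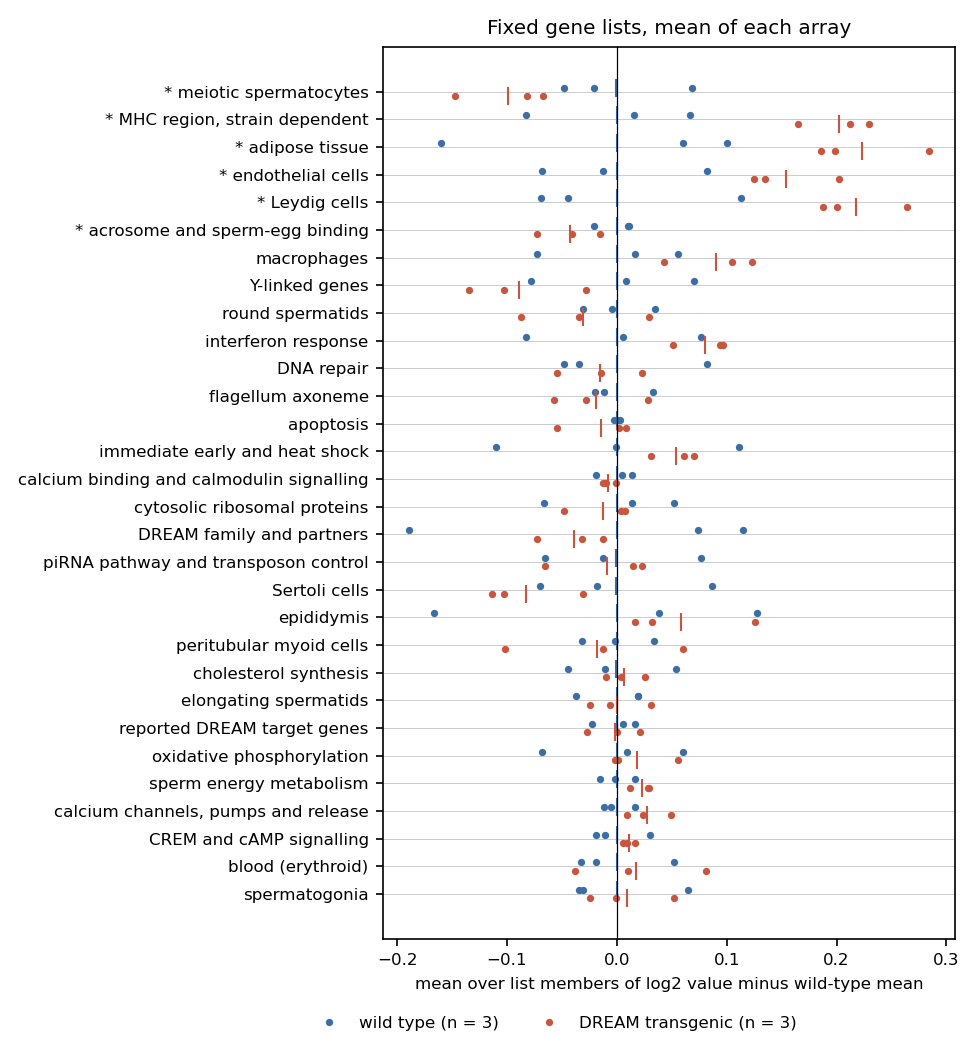
Mean over the members of each fixed gene list of the log2 value minus the wild-type mean (horizontal axis), for each of the 6 arrays; points are arrays, short bars are group means, blue for wild type and red for DREAM transgenic, and a star marks the 6 lists past the threshold with the preset correlation. The starred lists have small shifts, from a mean of -0.10 for meiotic spermatocytes to 0.22 for adipose tissue.

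In the remaining lists, 0 members passed over all genes or over the list alone (limma), and none passed as a set. Signalling and stress genes were CREM and cAMP signalling (22 genes, camera adjusted p = 0.912, Akap3 at 0.28 and Pde4a at -0.14), immediate early and heat shock (21, 0.439, Egr1 at 0.36 and Hspb1 at 0.15) and apoptosis (26, 0.439, Pmaip1 at 0.49 and Fasl at -0.22). They had 1, 1 and 2 members at an unadjusted p under 0.05. Genome maintenance genes were DNA repair (28, 0.43, Brca2 at -0.30 and Lig4 at -0.28) and the piRNA pathway (17, 0.642, Tdrd9 at -0.19 and Dnmt3l at 0.19), with 2 and 0 such members. Metabolic and translation genes were cholesterol synthesis (19, 0.764, Sc5d at 0.33 and Pmvk at -0.29), oxidative phosphorylation (39, 0.854, Ndufa2 at 0.20 and Uqcrb at -0.19), sperm energy metabolism (26, 0.854, Eno4 at 0.38 and Pkm at -0.11) and cytosolic ribosomal proteins (32, 0.54, Rps15 at -0.19 and Rps25 at -0.20). They had 2, 0, 1 and 0 such members. Y-linked genes (6, 0.178, Usp9y at -0.22 and Uty at -0.15) had 0.

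Called genes were spread over the chromosomes, and none passed Fisher's exact test after adjustment over chromosomes. The smallest adjusted p was 0.0888 for chromosome 12, which held 12 called genes among 622 measured against 4.97 expected, Serpina1b, Serpina1c, Serpina3a, Serpina5, Galc and Zfp386 among them. The 4 Serpina genes, of 1 family, lie within 8 measured genes, and the test counted each of them separately. Genes called at an adjusted p under 0.10 gave an excess on chromosome 12 (17 against 8.04 expected, adjusted p = 0.035) and a deficit on chromosome 10 (2 against 11.1 expected, adjusted p = 0.0349).

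The Gapdh 3' minus 5' difference was higher in every transgenic array than in any wild-type array, by 0.157 on average (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allows). The same measure for beta-actin was 0.47 ± 0.05 in wild type and 0.50 ± 0.03 in transgenic testis (SD, n = 3; exact permutation p = 0.7). The 18S ribosomal RNA probe sets read 8.75 ± 0.63 and 8.12 ± 1.32 (SD, n = 3; exact permutation p = 0.5).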

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

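The Gapdh covariate and the MHC list without B2m and Cd74 (mean 0.193, against 0.203 with them) were chosen only after the results were seen, and the other alternatives were fixed before. The 200 called probe sets became 306 with trend and robust eBayes, 1058 with array weights (600 higher and 458 lower), 317 at an adjusted p under 0.10, 76 at 2-fold or more and 18 (16 shared) with the Gapdh 3' minus 5' difference as a covariate. Leaving out 1 array gave 70 to 429, the highest without wild type replicate 2, where all 200 were among them. The share of calls that were higher was 38.5%, against 56.7% with array weights, 55.7% without wild type replicate 2 and 22.9% without wild type replicate 3. The 6 lists past the threshold became 3 without the lowest 60% of probe sets, 2 without probe sets that can match several transcripts, 0 with the Gapdh covariate, an estimated correlation or fry, and 0 to 7 when 1 array was left out. The chromosomes past the threshold went from 0 to 2 when genes at an adjusted p under 0.10 were counted. For all of these moves the cause was not tested.

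Directions turned in 3 places. With the Gapdh covariate the meiotic list mean went to 0.039 (adjusted p = 0.851) and Kcnip3 with its brighter probe set to -0.234 (adjusted p = 0.628), and without the lowest 60% of probe sets the endothelial mean went to -0.002 (adjusted p = 0.964); without the lowest 40% it was 0.09 (adjusted p = 0.461). When 1 array was left out, Kcnip3 ranged from 0.015 to 0.125 and from 0.068 to 0.208 with its probe sets, and the Gapdh difference from 0.125 to 0.185. Of 27 genes named as past the threshold, 0 changed direction and 10 stayed past it under each of the 15 settings that measured them, while 17 fell short with the Gapdh covariate. Of these 17, 9 had a change at least as large as before, such as Ssh1 (1.63 from 1.11) and Rd3 (-2.81 from -2.47), and 4 shrank to under 0.67 of it, Rcbtb2 (-0.93 from -1.82), Qrich1 (-0.84 from -1.73), Kcnab1 (0.51 from 1.07) and Fcgr3 (-0.51 from -0.82). The SEs of the 17 changed by 0.961 to 2.03 times, with a median of 1.78. For the 9 the call ended with a wider error, not a smaller change. With the replicate number as a block, 117 probe sets and 4 lists passed. Same-numbered arrays had correlations of -0.319, -0.065 and -0.012 in their deviations across probe sets, against -0.186 to 0.252 for other pairs. The numbers thus show no sign of pairing, though 3 arrays per group cannot exclude it. Dim transcripts have no detection call, and 3 arrays per group limit all of this.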

Other observations

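The tests of other probe sets of the called genes, of germ cell share, of RNA degradation, of immune lists and of the splits for gene lists were chosen after the results they bear on were seen, as were the genes in the next 2 paragraphs.

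There were 11 genes called by more than 1 probe set, 10 with every called probe set moving the same way and Pdxdc1 with opposite directions. Akna fell by 0.94 and 0.92 on the log2 scale with its probe sets (SE 0.10 and 0.10, adjusted p = 0.00448 and 0.00625), beside the fall of its opposite-strand transcript Aknaos. Zfp386, a zinc finger gene, fell by 1.25 and 1.04 with both of its probe sets (adjusted p = 0.00124 and 0.0194). Pde7a, a cAMP phosphodiesterase gene, fell by 1.25 and 1.10 with 2 probe sets (adjusted p = 0.000943 and 0.00944), but its 3 brighter probe sets read 0.00, -0.08 and -0.22 (adjusted p = 1, 0.982 and 0.835). Tc2n fell by 0.93 and 0.76 (adjusted p = 0.0137 and 0.0224) and read -0.31 and -0.25 with its others (adjusted p = 0.609 and 0.729). Camk2n1, which encodes an inhibitor of the calcium/calmodulin-dependent kinase CaMKII and stands in none of the fixed lists, rose by 0.63 and 0.59 (adjusted p = 0.0303 and 0.0313).

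Some neighbouring genes moved in opposite directions. On chromosome 7 Apoc1 rose by 0.83 (SE 0.10, adjusted p = 0.0112) while Apoc2 fell 4.00-fold. On chromosome 13 Paip1 rose by 1.04 with 1 dim probe set while 4833420G17Rik fell by 1.59 with 1 probe set and Tmem267 by 3.56 on the log2 scale, these 3 lying within 4 measured genes of the order used. Paip1 read 0.07 with its brightest probe set and 1.24 and 0.13 with its others (adjusted p = 0.971, 0.104 and 0.955). The other probe sets of 4833420G17Rik read -0.50 and -0.52 (adjusted p = 0.227 and 0.057). On chromosome 12 Serpina1b, Serpina1c, Serpina5 and Serpina3a all rose, by 1.27, 1.95, 0.89 and 1.84. The bile and drug transporter gene Abcc3 fell by 1.19 (adjusted p = 0.00448) and the calmodulin-like gene Calml4 by 1.07 (adjusted p = 0.0282).

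Among the calls, genes of different families lay within 10 measured genes of each other in 19 pairs, against a median of 10 and a 95th percentile of 16 in 10000 random draws (permutation p = 0.009). Without the lowest 40% of probe sets there were 22 pairs (median 15 and 95th percentile 21). Strain segments of the hybrid background would give such an excess. Runs of 3 or 4 called neighbours lay on chromosomes 4, 5, 8, 12 and 13, the run on chromosome 12 being of Serpina genes alone. An insertion site at 1 place would not give all of them. The runs were not compared with random draws and some may be chance, so they do not speak against such a site. The random draws do not allow for neighbouring genes that vary together, so the excess does not decide its cause. Other bright probe sets of the called genes moved by a median of 0.143 in the called direction, below 0.453, which is 0.5 times the called median of 0.905. The called probe set was the one of smallest p in a gene that passed, so selection alone would make the others move less. The gap therefore does not decide for a sequence variant under the probes or a changed transcript end, which stay open for part of the genes. Only 60 of the 145 called genes had another bright probe set. For the others, Tmem267, Cst9, Apoc2 and Sult1e1 among them, the question could not be tested. The other probe sets of Tspan18 and Ssh1 hardly moved, while those of Akna and Zfp386 moved with the called ones. Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, called 200 probe sets and the highest other called 0, but 10 splits are too few for a share under 0.05. An effect of active DREAM on these genes stays open, since a strain difference between the groups would follow the same arrays.

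The meiotic list was lower and the endothelial and adipose lists higher in transgenic testis, and 1 of the 10 splits, the real one, gave as many as 6 lists (the highest other gave 4), too few splits for a share under 0.05. A lower share of germ cells would raise every somatic list alike, yet the joined endothelial and adipose shift lay above that of the Sertoli (without Cst9) and peritubular myoid lists by 0.187 (SE 0.080 over arrays). An exact permutation test of that gap (two-sided) gave p = 0.1, the smallest that 3 against 3 allows. The gap was 0.192 (SE 0.104) without transgenic replicate 1 and 0.156 (SE 0.096) without transgenic replicate 3, within 2 SE of 0. It was lowest without wild type replicate 2, at 0.117 (SE 0.051). The endothelial and adipose lists in it were chosen because they rose. The Leydig (mean 0.22) and macrophage (mean 0.09) lists, above 0 as well, were left out. Of the germ cell lists, the meiotic shift was -0.098 (SE 0.043 over arrays). Spermatogonia stood at 0.009 (SE 0.04), round spermatids at -0.031 (SE 0.039) and elongating spermatids at 0 (SE 0.025). No fall of all germ cell lists alike was seen, but RMA forces the arrays to a near-common distribution. A fall shared by many transcripts could thus be hidden. The gap does not tell a change in germ cell share apart from one in these somatic types alone. Averaged over the rise of the endothelial and adipose lists and the fall of the meiotic list, the shift was 0.143 (SE 0.05), and with the Gapdh 3' minus 5' difference as a covariate it was 0.013 (SE 0.075). That difference did not overlap between the groups, and its slope within them was 0.83 (SE 0.416). The beta-actin 3' minus 5' difference, the other integrity measure, was only 0.027 higher in transgenic testis (exact permutation test, two-sided, p = 0.7). RNA degradation thus rests on Gapdh alone, and with that measure it cannot be told apart from genotype here.

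The MHC region list was higher in transgenic testis. More immune cells or interferon signalling may raise it, and the macrophage and interferon lists, which share 0 genes with it, had a joined shift of 0.086 (SE 0.035 over arrays). That shift was 0.069 (SE 0.039) without wild type replicate 2 and within 2 SE of 0 without wild type replicate 1 or transgenic replicate 1 or 2 as well, and Fcgr3 of the macrophage list fell by 0.82 on the log2 scale, so the arrays do not decide this. The highest and lowest probe sets of the same gene differed by more than 2 SE in 3 of 6 class I and class II genes (H2-Aa, H2-D1 and H2-K1). Extremes exceed 2 SE more easily with more probe sets, of which H2-D1 has 9 and H2-DMa 2. A haplotype that fits some probes better cannot be told apart from a change in level.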
